A study of Mus musculus with 18 samples.

How the data were processed

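RNA was sequenced from 18 samples of mouse bone marrow-derived dendritic cells (BMDC). Per the series design text, bone marrow was cultured with GM-CSF at 20 ng/ml and Flt3L at 100 ng/ml for 7 to 10 days, and cells were either sorted as DC1 (CD11c+ Xcr1+) or purified with an XCR1 antibody and magnetic beads. Which of these purifications each sample had is not stated, and Xcr1, a marker of type 1 conventional dendritic cells (cDC1), is therefore a gene the cells were selected on. Per the labels, each sample is WT or KO and was either a control or treated with lipopolysaccharide (LPS), a bacterial ligand of Toll-like receptor 4. The labels do not name the deleted gene, and they do not give the LPS dose or time. They also do not state whether replicates are separate cultures or animals, so each p-value measures the spread between samples as deposited.

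Per the labels' protocols, libraries of total RNA were made for the DNBSEQ platform and read as 150-base pairs. Per the submitters' processing notes, HISAT and Bowtie2 were used with the build GRCm39. Versions, the annotation and the program that counted reads are not given in the sources used here. The deposited table holds 16614 genes and, per the file headers, an estimated count, a TPM value and an FPKM value for each gene and library. The authors deposited the estimated counts without normalization, and 6.37% of the values are not whole at a tolerance of 0.001. The TPM columns deposited by the authors are scaled by transcript length to the same sum in every library, and the deposited FPKM values are scaled by transcript length and library total. Tests here used the estimated counts, rounded to whole numbers, and the TPM and FPKM values were left out because they do not keep the counting error. No genome of build GRCm39 was at hand, so no coordinates are given. Of the gene IDs in the table, 16495 were found in the RefSeq table of assembly GRCm38.p6, which was used for names and for gene properties only. How reads shared between near-identical genes were counted is not stated, which leaves the values of the Oas, Ifit and H2 families less certain than those of single-copy genes.

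Library totals lay between 25590104 and 27375189 estimated counts. Group means were 26.7 M for WT control (n = 4), 27.1 M for KO control (n = 4), 26.3 M for WT LPS (n = 5) and 26.0 M for KO LPS (n = 5). A gene passed the filter of edgeR (minimum count 10, minimum total 15) or was left out, which kept 11989 genes. TMM factors averaged 1.36 in WT control, 1.32 in KO control, 0.814 in WT LPS and 0.769 in KO LPS, so LPS libraries gave more of their counts to a limited set of abundant genes. CPM values given below are scaled with these factors. The biological coefficient of variation was 0.0934. Between replicates of a group, counts differed by more than counting error alone would give, with a chi-square per degree of freedom of 2.85 to 84.5 over 32 pairs.

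A quasi-likelihood model (edgeR 4.0.16 under R 4.3.3) was fitted to all 18 libraries with a mean for each group and no other term. From it came 5 contrasts, namely KO against WT in control and with LPS, LPS against control in WT and in KO, and the interaction of genotype and LPS. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Fold changes are log2 values with their standard errors (SE). The levels of Stat3, Stat5a and Stat5b were also compared between genotypes with exact two-sided permutation tests of log2 CPM (prior count 2).

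Before the data were examined, 24 gene lists were written. They were STAT3-linked genes, STAT5 and GM-CSF-linked genes, JAK-STAT components and receptors, co-stimulation and DC maturation, inflammatory cytokines, chemokines, type I interferon response, MHC class I presentation, MHC class II presentation, NF-kB and LPS feedback, tolerogenic and inhibitory genes, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, cholesterol synthesis and handling stress genes. The remaining lists held markers of cDC1, cDC2, monocytes and macrophages, plasmacytoid DC, neutrophils, mast cells and basophils, lymphocytes, and erythroid cells and platelets. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a contrast. The same test with an estimated correlation called no list in any of the 5 contrasts, where the preset one called 7, 10, 12, 12 and 6, in the order given above. The fry test, which asks whether a list's genes move on balance in a common direction, was run beside it. The design, the tests, the filter, the alternatives other than those named as added, and the rule for named genes were fixed at the same time as the lists.

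Genes are named by that rule. It takes Stat3, Stat5a, Stat5b, Socs3, Cish and Il10 whatever their values, and a further gene that is not reported here. It adds in each contrast the 5 called genes with the highest and the 5 with the lowest fold change that reach 5 CPM and do not overlap between the groups, leaving out predicted genes and pseudogenes, without the overlap condition for the interaction. From each list it takes the called members with the smallest adjusted p in each direction, or the most abundant members as values where none was called. Any other gene is said to have been chosen after its values were seen.

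The scripts' tests were checked on simulated data drawn from the real means and dispersions with known changes. At a fold of 1.5, edgeR recovered 88.1% of changed genes for KO against WT in control (11918 genes), 88.1% with LPS (11913 genes) and 64.2% for the interaction (11919 genes). Of its calls in these simulations, 2.27%, 7.11% and 5.97% were false. The simulated counts held no shift shared across the genes of a library. These false shares therefore need not hold for the LPS and interaction tests, where WT LPS replicate 2 lay apart from its group. At a fold of 1.25 it recovered 41.8%, 55.2% and 11.9%. In a simulation of KO against WT with LPS that held a trend with length, edgeR without a correction called 1806 unchanged and 169 changed genes of 11922, and with the GC and length correction 17 and 159.

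Alternatives were DESeq2 size factors in edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the groups compared, leaving out each library in turn, and leaving out the libraries numbered 5 and 7, whose run of library numbers has no control samples. A further pair of fits used a replicate block, by title number or by run of library numbers. Alternatives added after seeing the data were total-count scaling and a correction of each library for GC content and gene length with splines of 5 degrees of freedom, which used 11589 of the 11989 genes tested. Whether the numbers pair the samples was checked by correlating deviations from group means. For LPS against control in WT, samples of the same run of library numbers correlated at 0.14 to 0.27 in 4 of 4 pairs, above the limit of 0.1. In no other comparison or numbering did every pair pass that limit.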

Results

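The series measured gene expression in XCR1-purified BMDC of WT and KO genotype, each kept as a control or treated with LPS. Its title names the balance of STAT5 and STAT3, transcription factors activated by cytokine receptors, as the subject. The groups held 4 WT control, 4 KO control, 5 WT LPS and 5 KO LPS samples, with 25590104 to 27375189 estimated counts each.

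Stat3 (gene ID 20848), Stat5a (20850) and Stat5b (20851) were read in every library, so no library lacked transcript of these genes. In control samples, Stat3 averaged 173 CPM in WT and 170 CPM in KO (log2 fold change -0.03 ± 0.08 SE, edgeR adjusted p = 0.94). Stat5a averaged 70.8 and 74.2 CPM, and Stat5b 83.3 and 79.9 CPM, with exact permutation p values of 0.686 and 0.6. With LPS, Stat3 was lower in KO, at 781 CPM against 1002 CPM in WT (-0.36 ± 0.07, adjusted p = 0.0035), and every KO library lay below every WT library. The exact permutation p for Stat3 with LPS was 0.00794, the smallest that 5 samples against 5 can give, and 0.0476 after adjustment over 6 such tests. Stat5a with LPS was 695 CPM in WT and 1013 CPM in KO (0.54 ± 0.16, adjusted p = 0.039), and Stat5b was 237 and 308 CPM (0.38 ± 0.10, adjusted p = 0.019). The exact permutation p was 0.0397 for Stat5a and 0.0159 for Stat5b, or 0.0794 and 0.0476 after adjustment, so Stat5a did not pass in that test. The genotypes overlapped through WT LPS replicate 2. Its Stat5a level of 1018 CPM lay above KO LPS replicates 2, 3 and 5 (786, 871 and 998 CPM). The other WT LPS libraries lay at 503 to 720 CPM. For Stat5b, WT LPS replicate 2 lay at 297 CPM, the other WT LPS libraries at 205 to 253 CPM and the lowest KO LPS library at 261 CPM. The Stat5a call ended without any of WT LPS replicates 1, 3, 4 and 5 or KO LPS replicates 1, 4 and 5 (adjusted p up to 0.13), and that of Stat5b without WT LPS replicate 1, 3 or 4 or KO LPS replicate 1 (up to 0.065). In the interaction test, none of Stat3 (-0.33 ± 0.11, adjusted p = 0.10), Stat5a (0.48 ± 0.25, 0.31) and Stat5b (0.44 ± 0.15, 0.11) passed. Counts per gene cannot show a deletion of only some exons, so these levels neither identify the deleted gene nor check the labels.

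**Figure D1:**
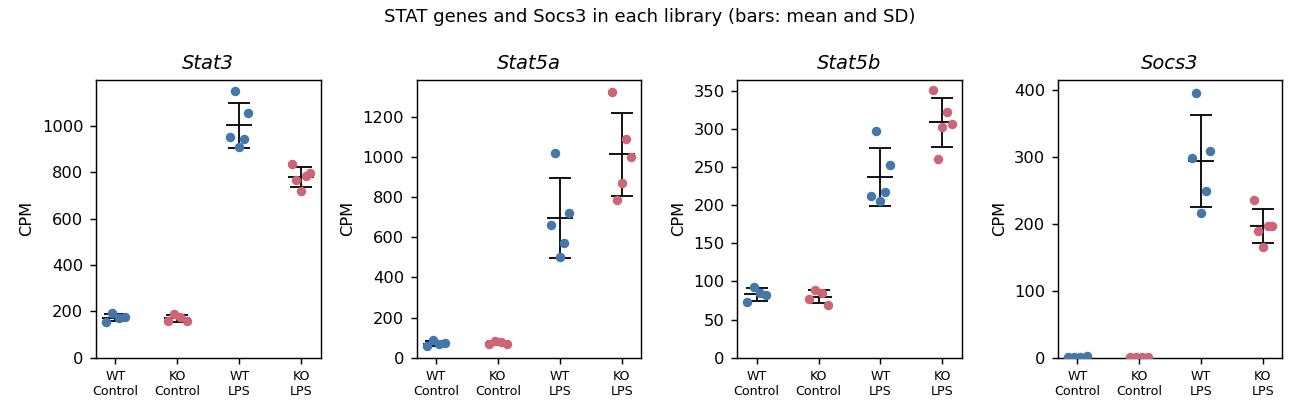
Expression in CPM (linear axis from 0) of Stat3, Stat5a, Stat5b and Socs3 in each library of the 4 groups; points are libraries, bars the mean and SD. Stat3 averaged 781 CPM in KO LPS and 1002 CPM in WT LPS, while the control groups averaged 170 and 173 CPM.

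The comparison of genotypes without LPS asks how KO cells differed before stimulation. Interferon-stimulated genes were the largest group of listed genes that rose in KO. Irf7 (gene ID 54123), a transcription factor that amplifies interferon production, rose from 9.51 to 24.3 CPM (1.35 ± 0.16, edgeR adjusted p = 6.9e-05, n = 4 per genotype). Oas3 (gene ID 246727), an antiviral oligoadenylate synthetase, rose from 11.2 to 29.7 CPM (1.40 ± 0.13, adjusted p = 7.9e-06), and the interferon-induced Ifi27l2a rose from 3.17 to 7.93 CPM. The chemokine receptor Xcr1 (gene ID 23832), on which the cells had been selected, fell from 175 to 109 CPM (-0.68 ± 0.07, adjusted p = 1.3e-05).

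Of 25 tested members of the type I interferon response, 12 rose in KO control samples, and 18 rose when adjusted over the list alone. Their median log2 fold change was 1.07 (camera adjusted p = 1.0e-39, adjusted p = 0.094 with an estimated correlation). Members of MHC class II presentation rose less, with 4 of 14 called, 8 when adjusted over the list alone, and a median of 0.21 (camera adjusted p = 2.1e-06, adjusted p = 0.26 with an estimated correlation). H2-Ob, a subunit of the peptide-loading modulator H2-O, rose by 0.28 ± 0.05. In MHC class I presentation, 2 of 18 rose, 5 when adjusted over the list alone, among them H2-K1, a class I heavy chain (0.34 ± 0.05, adjusted p = 0.00061). That list had a median of 0.15 (camera adjusted p = 2.1e-06, adjusted p = 0.58 with an estimated correlation). Without WT LPS replicate 2, which adds to the estimate of spread only, 8 class II and 4 class I members rose, and limma-voom called 7 class II members.

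Among tolerogenic and inhibitory genes, Lgals9, which encodes galectin-9, rose from 8.90 to 16.9 CPM (0.92 ± 0.12, adjusted p = 0.00017) as the called member of 15, with 2 rising when adjusted over the list alone. The list median was 0.17 (camera adjusted p = 0.025, adjusted p = 0.78 with an estimated correlation). Of 17 STAT5 and GM-CSF-linked genes, Ccl22, a chemokine that attracts regulatory T cells, rose by 0.95 ± 0.20 (adjusted p = 0.014), alone also when adjusted over the list alone. Its call ended without WT control replicate 2 or 3 (adjusted p up to 0.079). The median of that list was 0.17 (camera adjusted p = 0.018, adjusted p = 0.72 with an estimated correlation). No member of the 15 STAT3-linked genes passed in edgeR, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.96). The cytokine Il18 rose by 0.58 ± 0.11 (adjusted p = 0.0080). Without WT LPS replicate 2, 2 tolerogenic and inhibitory genes rose.

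Among cell cycle genes, Mki67, a marker of proliferating cells, fell by 0.62 on the log2 scale (SE 0.13, adjusted p = 0.010) as the called member of 20 in KO control samples, and 10 members fell when adjusted over the list alone. The list median was -0.39 (camera adjusted p = 1.4e-07, adjusted p = 0.58 with an estimated correlation). Cenpe, a mitotic kinesin, fell from 71.9 to 45.0 CPM (-0.67 ± 0.11, adjusted p = 0.0023). Of 16 genes of cholesterol synthesis, 1 fell, 3 when adjusted over the list alone, with a median of -0.18 (camera adjusted p = 1.2e-06, adjusted p = 0.58 with an estimated correlation). Without WT LPS replicate 2, 13 cell cycle and 7 cholesterol genes fell, and without WT control replicate 3 the call of Mki67 ended (adjusted p = 0.060). WT control replicate 4 stood apart from the other WT control samples in the mean level of the cell cycle list (6.36 against 6.53 in the nearest, log2 CPM) and of the interferon list (1.41 against 1.06).

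Over all genes, 289 of 11989 were called between genotypes in control samples, 226 higher and 63 lower in KO, with 1665 at an unadjusted p under 0.05. A fold of at least 2 was reached by 33 of the higher and 6 of the lower genes. Foxj1, a regulator of motile cilia genes, had the highest fold change of the called genes that reach 5 CPM and do not overlap between genotypes, predicted genes and pseudogenes aside (2.06 ± 0.27, 2.93 to 12.3 CPM), followed by Hr (1.47 ± 0.21), and Tspoap1 (-0.98 ± 0.10) and Fndc5 (-0.72 ± 0.10) were among the lowest of these. The share of calls that were higher was 78.2%, 65.7% with the GC and length correction, 54.7% with only the control groups in the fit and 52.6% without the libraries numbered 5 and 7. The log2 fold change went with gene length (Spearman -0.264) and GC content (0.137) across genes, so the excess of higher calls is not separated from these trends. The count was 175 without WT control replicate 1, 158 without KO control replicate 2, 114 without WT control replicate 3, 171 without KO control replicate 3 and 751 without WT LPS replicate 2.

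The comparison of genotypes with LPS asks how KO cells differed after stimulation. Il12b (gene ID 16160), the shared subunit of IL-12 and IL-23, was higher in KO at 2597 CPM against 1190 CPM (1.13 ± 0.20, edgeR adjusted p = 0.0011, n = 5 per genotype). Ccl17 (gene ID 20295), a chemokine for CCR4-bearing T cells, rose from 84.4 to 207 CPM (1.30 ± 0.20, adjusted p = 0.00024). Socs3 (gene ID 12702), a feedback inhibitor induced by STAT3, fell from 293 to 197 CPM (-0.58 ± 0.13, adjusted p = 0.0065). Bcl3 (gene ID 12051), an atypical IkB protein, fell from 424 to 276 CPM (-0.62 ± 0.07, adjusted p = 1.3e-05). Marchf1 (gene ID 72925), the ubiquitin ligase that removes MHC class II from the cell surface, fell from 131 to 62.7 CPM (-1.06 ± 0.07, adjusted p = 3.3e-09).

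Of 15 tested STAT3-linked genes, 6 fell in KO with LPS, over all genes and when adjusted over the list alone (median -0.19, camera adjusted p = 0.0023, adjusted p = 0.745 with an estimated correlation). They included Il1r2, a decoy receptor for IL-1 (-0.45 ± 0.08). Of 17 STAT5 and GM-CSF-linked genes, 5 rose, and 5 rose and 1 fell when adjusted over the list alone (median 0.19, camera adjusted p = 0.034, adjusted p = 0.745 with an estimated correlation). Ccl22 rose from 7102 to 12858 CPM (0.86 ± 0.18), and Cish, a STAT5-induced feedback inhibitor, rose from 9.42 to 14.9 CPM (0.67 ± 0.17, adjusted p = 0.014). The Cish call ended without KO LPS replicate 1 (adjusted p = 0.056). Among 23 JAK-STAT components and receptors, 5 rose and 4 fell, or 8 and 5 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.79). Jak3 (gene ID 16453), a kinase of common gamma chain receptors, fell from 103 to 57.5 CPM (-0.84 ± 0.08, adjusted p = 5.2e-07), and Flt3, the receptor of the growth factor in the medium, fell by 0.26. Il10 averaged 1.15 CPM in WT and 1.37 CPM in KO with LPS, and under 0.01 CPM in both control groups (adjusted p = 0.63 with LPS). Without WT LPS replicate 2, 8 STAT5 and GM-CSF-linked genes rose and 2 fell, and 10 JAK-STAT genes rose and 6 fell.

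Of 13 inflammatory cytokines, 4 rose in KO, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.0014, adjusted p = 0.745 with an estimated correlation). Tnfsf15, a TNF family cytokine, rose from 212 to 413 CPM (0.96 ± 0.14). Of 19 genes of co-stimulation and DC maturation, 4 rose, 6 when adjusted over the list alone (median 0.18, camera adjusted p = 0.0027, adjusted p = 0.745 with an estimated correlation). Cd80, a ligand of CD28 and CTLA-4, rose from 125 to 208 CPM (0.73 ± 0.10), and Icosl, the ligand of ICOS, from 754 to 1069 CPM (0.50 ± 0.07). In NF-kB and LPS feedback, 5 of 21 rose and 1 fell, or 8 and 1 when adjusted over the list alone (median 0.11, camera adjusted p = 0.011, adjusted p = 0.745 with an estimated correlation). Tnip1, an inhibitor of NF-kB signalling, rose by 0.40 ± 0.05, and Zfp36, which destabilises cytokine mRNA, fell by 0.33. Of 13 chemokines, 2 rose, also when adjusted over the list alone (camera adjusted p = 0.24). DESeq2 called 7 co-stimulation genes. Without WT LPS replicate 2, 9 cytokines, 11 co-stimulation genes, 9 NF-kB genes and 4 chemokines rose. In mean log2 CPM of these lists, that WT library lay above every KO LPS library. It stood at 6.22 against at most 6.12 for cytokines, 8.14 against 7.97 for co-stimulation and 7.17 against 6.96 for NF-kB genes.

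Of 25 interferon response genes, 2 rose with LPS, 1 when adjusted over the list alone (median 0.20, camera adjusted p = 0.00043, adjusted p = 0.745 with an estimated correlation). Ifi44 rose from 74.1 to 105 CPM (0.51 ± 0.09). In MHC class I presentation, 3 of 18 rose, also when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.745 with an estimated correlation), with a median of 0.07 that turned to -0.0035 with total-count scaling. Tap2, a peptide transporter, rose by 0.23 ± 0.05. In MHC class II presentation, 2 of 14 rose and 2 fell, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.39), and the thiol reductase Ifi30 fell from 103 to 57.0 CPM (-0.85 ± 0.10). Its median was 0.03, or -0.04 with total-count scaling, and its mean and test were negative. Of 20 cell cycle genes, 7 fell, and 18 when adjusted over the list alone (median -0.45, camera adjusted p = 2.7e-06, adjusted p = 0.745 with an estimated correlation). Of the cell cycle genes, DESeq2 called 12 and limma-voom 1, so most of these calls rest on the test used. Limma-voom called 4 interferon genes and DESeq2 8 class II genes. Without WT LPS replicate 2, 18 interferon genes, 8 class I and 6 class II genes rose, and 19 cell cycle genes fell. That WT library lay above every KO LPS library in the interferon list (9.31 against at most 9.13, mean log2 CPM). In the cell cycle list it lay below every one (4.69 against at least 4.88).

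Of 18 cDC1 markers, 2 rose and 6 fell in KO with LPS, or 3 and 9 when adjusted over the list alone (median -0.18, camera adjusted p = 0.0027, adjusted p = 0.745 with an estimated correlation). Xcr1, the marker used for purification, fell from 428 to 281 CPM (-0.61 ± 0.06), and Naaa (gene ID 67111), a lysosomal amidase, fell from 986 to 514 CPM (-0.94 ± 0.08). Cadm1, an adhesion molecule, rose from 113 to 155 CPM (0.46 ± 0.06). In control samples, 2 cDC1 markers had risen and Xcr1 alone had fallen (camera adjusted p = 0.42). Of 10 cDC2 markers, 2 fell with LPS, also when adjusted over the list alone (camera adjusted p = 0.071), Itgam by 0.74 and Clec12a by 0.48, and of 17 markers of monocytes and macrophages Ccr2 fell by 0.47 (camera adjusted p = 0.65). Of 5 tested lymphocyte markers, 2 rose, also when adjusted over the list alone (median 0.51, camera adjusted p = 0.045, adjusted p = 0.745 with an estimated correlation), at low levels such as 3.08 and 4.26 CPM for Cd4. DESeq2 called 1 of them, and the call of Cd4 ended without WT LPS replicate 1 or 4 or KO LPS replicate 2 or 5 (adjusted p up to 0.065).

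Over all genes, 1294 of 11989 were called between genotypes with LPS, 635 higher and 659 lower in KO. A fold of at least 2 was reached by 17 higher and 45 lower genes. Slc15a2 (gene ID 57738), a peptide transporter, had the highest fold change of the called genes that reach 5 CPM and do not overlap between genotypes, predicted genes and pseudogenes aside (2.25 ± 0.16, 10.6 to 50.5 CPM), followed by Ccl17 and Grhl1 (1.16 ± 0.16). The lowest of these were Gpr146 (-1.92 ± 0.12), Sema6b (-1.83 ± 0.24), Olfm1 (-1.69 ± 0.10) and Flot1 (-1.57 ± 0.08). The share of calls that were higher was 49.1%, 23% with total-count scaling and 62.4% with the GC and length correction. The count was 805 without KO LPS replicate 1 and 3344 without WT LPS replicate 2.

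The genotype effects in the 2 treatments rest on separate libraries, although WT libraries of the same run of library numbers deviated together, so the lists need not be independent. Of the genes higher in KO, 45 were called in both treatments where 12.0 would be expected of independent lists, and of those lower in KO, 20 against 3.46. The direction was opposite for 6 genes.

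**Figure D2:**
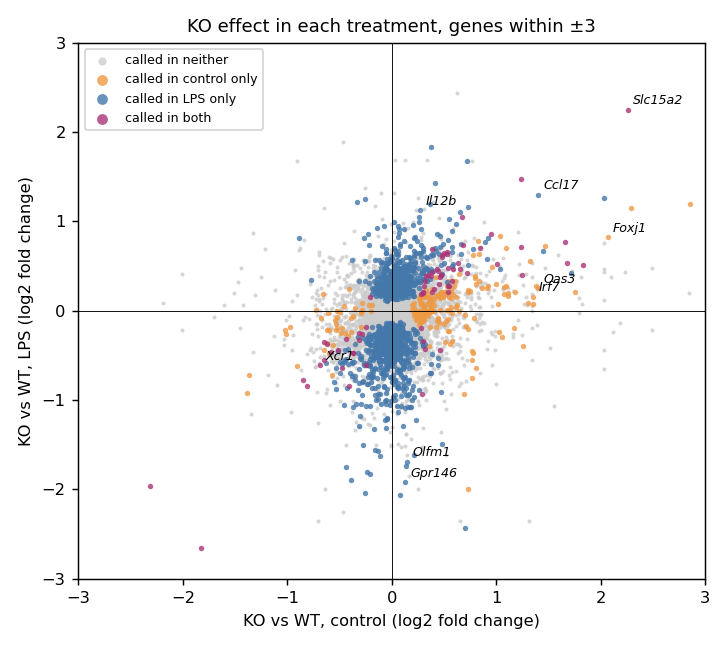
Log2 fold change of KO against WT in control samples (horizontal) and with LPS (vertical), a point per gene, coloured by where edgeR called it; 8 of 11989 genes lie outside the axes at 3. Slc15a2 lies high on both axes, Irf7 and Oas3 (1.35 and 1.40 in control) to the right, and Gpr146 and Olfm1 (-1.92 and -1.69 with LPS) at the bottom.

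**Figure D3:**
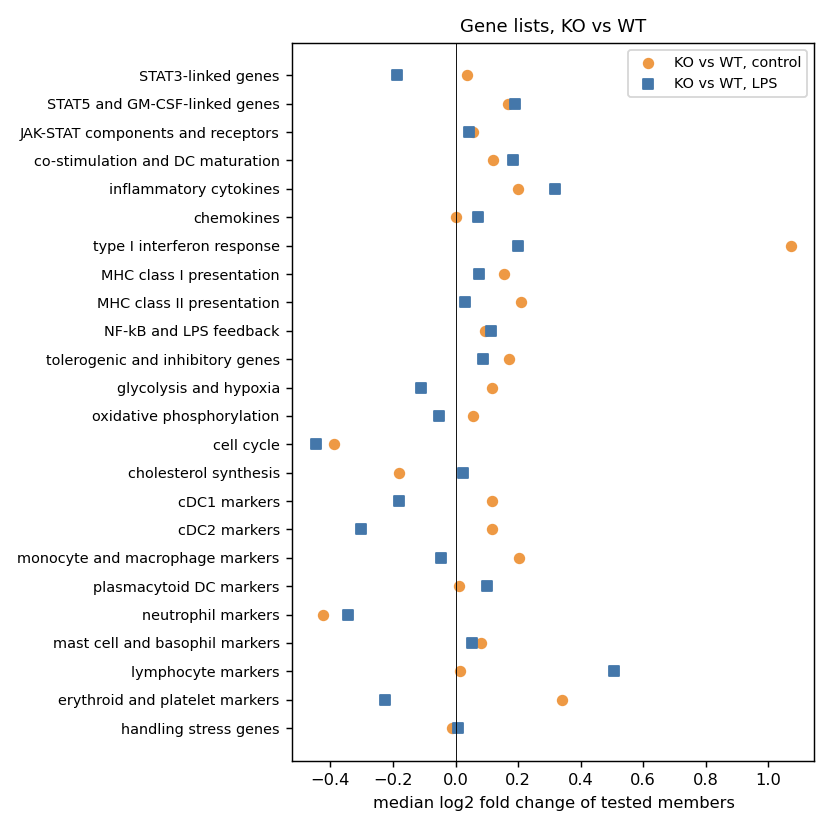
Median log2 fold change of KO against WT over the tested members of each of the 24 lists, in control samples (circles) and with LPS (squares). The type I interferon response lies at 1.07 in control and 0.20 with LPS, and the cell cycle list at -0.39 and -0.45.

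The comparison of LPS with control in WT measures the response of these cells to stimulation. Cxcl10 (gene ID 15945), an interferon-induced chemokine, rose from 0.131 to 1155 CPM (13.06 ± 0.26, edgeR adjusted p = 2.2e-19, 4 control and 5 LPS samples). Cxcl9 rose from 0.612 to 3940 CPM, and the antiviral gene Rsad2 from 0.639 to 1214 CPM. Cd40, a co-stimulatory receptor, rose from 2.96 to 1354 CPM (8.84 ± 0.19), and the cytokine Tnf from 1.53 to 1052 CPM (9.42 ± 0.17). The kinase gene Map2k6 fell from 25.3 to 0.101 CPM (-7.88 ± 0.17), and the prostaglandin receptor Ptger3 fell from 16.8 to 0.202 CPM. Stat3 (2.53 ± 0.09), Stat5a (3.29 ± 0.20), Stat5b (1.51 ± 0.11) and Socs3 (7.49 ± 0.21) all rose.

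In WT, all 25 interferon response genes rose (median 8.37, camera adjusted p = 2.8e-29, adjusted p = 0.096 with an estimated correlation). The 19 genes of co-stimulation and DC maturation (median 3.74, adjusted p = 2.0e-13), the 13 cytokines (7.39, 8.8e-07), the 13 chemokines (7.72, 1.5e-07) and the 18 genes of MHC class I presentation (1.84, 3.3e-13) rose without exception. With an estimated correlation, the adjusted p of these 4 lists was 0.11, 0.23, 0.21 and 0.096. In NF-kB and LPS feedback, 20 of 21 rose and Tlr4, the LPS receptor, fell by 1.76 (camera adjusted p = 1.3e-14, adjusted p = 0.096 with an estimated correlation). Of 15 STAT3-linked genes, 13 rose and 1 fell (median 2.48, camera adjusted p = 1.5e-07, adjusted p = 0.076 with an estimated correlation). JAK-STAT genes rose in 18 of 23 and fell in 3, Ifngr1, a chain of the interferon gamma receptor, by 3.23 (camera adjusted p = 3.5e-05, adjusted p = 0.11 with an estimated correlation). The counts for all of these lists were the same when adjusted over the list alone.

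Of 16 cholesterol synthesis genes, 15 rose in WT, Hmgcs1, an early enzyme of the pathway, from 171 to 1630 CPM (list median 2.38, camera adjusted p = 2.5e-09, adjusted p = 0.21 with an estimated correlation). Of 20 cell cycle genes, 18 fell, the replication helicase subunit Mcm6 by 1.62 (median -0.99, camera adjusted p = 0.037, adjusted p = 0.64 with an estimated correlation). Tolerogenic and inhibitory genes rose in 11 of 15 and fell in 2, Lgals9 rising by 5.57 ± 0.13 (camera adjusted p = 0.0080, adjusted p = 0.52 with an estimated correlation). Handling stress genes rose in 9 of 13 and fell in 1, the stress-induced factor Atf3 rising from 21.9 to 413 CPM (camera adjusted p = 0.019, adjusted p = 0.096 with an estimated correlation). Of 17 STAT5 and GM-CSF-linked genes, 12 rose and 4 fell, Ccl22 rising by 6.80 and the phosphatase Dusp6 falling, at -4.84 (camera adjusted p = 0.12, and 0.045 with the block of library numbers). Of 20 genes of glycolysis and hypoxia, 15 rose and 3 fell (camera adjusted p = 0.062, and 0.035 with that block), with a median of 0.74 that turned to -0.0071 with total-count scaling. Of 20 genes of oxidative phosphorylation, 15 rose and 2 fell (camera adjusted p = 0.057), and 8 of 14 in MHC class II presentation rose and 3 fell (0.18). Their medians of 0.48 each turned to -0.26 and -0.27 with total-count scaling. The list-alone adjustment gave the same counts, adjusted over the list alone, for each of these lists.

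Marker lists were mixed in WT with LPS, and none passed camera. Of 18 cDC1 markers, 3 rose and 12 fell, the endocytic receptor Ly75 rising by 3.13 and Septin3 falling, at -3.67 (camera adjusted p = 0.18). Xcr1, the purification marker, rose from 175 to 428 CPM. Of 10 cDC2 markers, 4 rose and 3 fell (camera adjusted p = 0.61), with a median of 0.02 that turned to -0.73 with total-count scaling, -0.22 with the GC and length correction and -0.03 without WT LPS replicate 2. Of 17 monocyte and macrophage markers, 12 rose and 2 fell (0.50), and of 8 plasmacytoid DC markers 4 rose and 2 fell (0.17), Bst2, itself induced by interferon, rising by 3.44. Of 6 neutrophil markers 1 rose (0.80), Mmp9, from 1.55 to 4.01 CPM, and of 2 mast cell and basophil markers Hdc rose and Kit fell (0.50). Of 5 lymphocyte markers, 4 rose and 1 fell (0.37), Ms4a1 to 2.72 CPM, and both tested erythroid and platelet markers rose (0.62), Pf4 to 3.94 CPM. The calls of Mmp9 and Pf4 ended with total-count scaling (adjusted p = 0.090 and 0.29). These counts were unchanged when adjusted over the list alone.

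Over all genes, 10246 were called in WT, 4884 higher and 5362 lower with LPS, and 2325 and 2868 by at least a fold of 2. Total-count scaling in place of TMM moved the median log2 fold change of all genes from -0.06 to -0.80 and left 22.1% of calls higher in place of 47.7%, so directions of small changes hold relative to the TMM scale.

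LPS was also compared with control in KO cells, 4 control and 5 LPS samples. Cxcl10 (12.26 ± 0.24) and Cxcl9 (11.98 ± 0.29) rose most among genes chosen by the rule, with Il27 reaching 63.5 CPM and the activation marker Cd69 95.4 CPM. Stat3 rose by 2.20 ± 0.08, Stat5a by 3.77 ± 0.20 and Stat5b by 1.95 ± 0.11. Map2k6 (-8.13 ± 0.18) and Ptger3 (-7.29 ± 0.21) fell. All 25 interferon response genes rose (median 7.24, camera adjusted p = 5.6e-25, adjusted p = 0.11 with an estimated correlation), as did the 19 genes of co-stimulation and DC maturation (median 3.71, camera adjusted p = 9.2e-13, adjusted p = 0.12 with an estimated correlation). Of 16 cholesterol synthesis genes, 15 rose (median 2.57, camera adjusted p = 3.6e-10, adjusted p = 0.18 with an estimated correlation), and of 20 cell cycle genes 15 fell (median -1.10, camera adjusted p = 0.038, adjusted p = 0.76 with an estimated correlation). These counts also held when adjusted over the list alone. In edgeR 10338 genes were called, 4794 higher and 5544 lower. In both genotypes, 4524 genes rose where 1953 would be expected of independent lists, and 5154 fell against 2480. With total-count scaling the median over all genes moved from -0.10 to -0.88, and 22.3% of calls were higher in place of 46.4%.

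The interaction asks whether the genotype effect differed between treatments. The genotype effect was lower with LPS than in control for 8 of 25 interferon genes, 12 when adjusted over the list alone (median -0.85, camera adjusted p = 3.1e-11, adjusted p = 0.53 with an estimated correlation). DESeq2 called 10 of these genes and limma-voom 3. By fry the interferon list did not pass (adjusted p = 0.062). Oas3 differed by -1.15 and the exonuclease Isg20 by -0.89. Olfm1 (-1.83 ± 0.14, edgeR adjusted p = 1.0e-07) and Gpr146 (-2.05 ± 0.16, adjusted p = 1.5e-07) were lower in KO with LPS, while in control Olfm1 was at 137 CPM in WT and 151 CPM in KO. The genotype effect on Marchf1 (-1.12) and Naaa (-1.09) was also lower with LPS. It was higher for the homeobox gene Zfhx2 (1.07 ± 0.15, adjusted p = 0.00033) and for Nfatc2ip (0.95 ± 0.15), which rose to 57.3 and 54.8 CPM in KO LPS.

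In edgeR 458 genes were called for the interaction, 124 higher and 334 lower. The share that were higher was 27.1%, 42.9% with DESeq2 size factors, 57.2% with the GC and length correction and 51.9% without the libraries numbered 5 and 7, so the balance of directions depended on the scaling and the libraries. The count was 208 without WT control replicate 3, 304 without WT control replicate 4, 281 and 305 without KO control replicates 3 and 4, 287, 298 and 279 without KO LPS replicates 1, 4 and 5, and 1501 without WT LPS replicate 2.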

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

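Tests of explanations, total-count scaling and the GC and length correction were chosen only after the results were seen, while the interaction, the spread within groups and the list tests were planned.

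The difference in genotype effect between treatments (KO effect with LPS minus that in control, log2, edgeR interaction test) passed for 26 genes that the naming rule takes because they passed. Stat3, Stat5a and Stat5b, which the rule takes whatever their values, did not pass. The difference also passed for other genes named elsewhere, such as Irf7 (-1.19) and Flot1 (-1.44). It was higher with LPS for Nes (1.12), Slco4a1 (1.09), Zfhx2 (1.07), Nfatc2ip (0.95), Slc9a5 (0.95), Hmgcs1 (0.38) and Tnip1 (0.37). It was lower for Vwa1 (-2.15), Gpr146 (-2.05), Olfm1 (-1.83), Sema6b (-1.62), Ptger2 (-1.51), Marchf1 (-1.12), Naaa (-1.09), Gcsam (-1.06), Cd300a (-0.98), Ifi30 (-0.91), Oas3 (-1.15), Isg20 (-0.89), Il21r (-1.07), Lgals9 (-0.65), Ccr2 (-0.63), Kit (-0.48), Il1r2 (-0.46), Flt3 (-0.31) and H2-K1 (-0.26). Leaving out 1 library at a time ended the call of Ccr2 in 13 of 18 fits (adjusted p up to 0.077), of Hmgcs1 in 9 (0.096), of Flt3 in 8 (0.064), of H2-K1 in 8 (0.086), of Il1r2 without WT control replicate 2 or 3 (0.067) and of Lgals9 without WT control replicate 3 (0.058). By camera, 6 lists passed in the interaction: type I interferon response (median -0.85), MHC class II presentation (-0.21), glycolysis and hypoxia (-0.24), cDC1 markers (-0.17), STAT3-linked genes (-0.21) and cholesterol synthesis (0.25). With an estimated correlation the lowest adjusted p of the 24 lists was 0.533.

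In 6 of 132 groups of values per sample (list means, library measures and levels of single genes), a sample lay further from its replicates than Dixon's 95% limit, where chance gives 6.6. These 6 were list means. In log2 CPM, WT control replicate 4 was high in the interferon list (1.41, nearest 1.06) and the handling stress list (2.96, nearest 2.67) and low in the cell cycle list (6.36, nearest 6.53). KO control replicate 4 was low in JAK-STAT genes (6.59, nearest 6.70), WT LPS replicate 5 high in neutrophil markers (3.05, nearest 0.42), and KO LPS replicate 1 low in handling stress genes (4.49, nearest 4.72). Of the same run of library numbers as WT LPS replicate 5, WT control replicate 4 was also the highest of its group in neutrophil markers (1.93, nearest -0.42), as was KO control replicate 4 (0.159, nearest -0.47), while KO LPS replicate 5 (0.833) was not above KO LPS replicate 2 (0.866).

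Interferon genes were higher in KO control samples. RNA of LPS-treated cells was tested as the source through 8 other LPS-induced genes: a share of 0.370% would be needed, and these genes rose by 0.0382 of what it predicts (quartiles 0.0229 to 0.144). More plasmacytoid DC among the sequenced cells were tested through 7 markers other than Bst2. Their median was 0.00695 (SD 0.265), against 1.07 for the interferon list. Both tests argue against these sources of the RNA. The cells were purified before sequencing, so the markers cannot show how many plasmacytoid DC the cultures held, and that number stays open. The genotype itself may be the cause, which remains a hypothesis, and differences between cultures stay open because the labels do not name them.

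WT LPS replicate 2 lay apart from the other WT LPS libraries. Over the 3344 genes called without it, its median position between the other WT libraries (0) and KO (1) was 1.11. At the 50 genes with the smallest p in that fit it was 0.159 (quartiles -0.137 to 0.325), which argues against a library of KO cells. A mixture with a small share of KO cells is not excluded, because it would also place the library a little above 0. A shift shared by its run of library numbers was tested through KO LPS replicate 2, which lay at 1.09 on the LPS axis, inside the 1.05 to 1.12 of the other KO libraries, while WT LPS replicate 2 lay at 1.13 and the other WT libraries at 0.969 to 1.04. WT and KO LPS replicates 2 still deviated together from their group means (correlation 0.187, above the limit of 0.1). Each was the highest of its group in monocyte and macrophage markers (5.75 and 5.58, mean log2 CPM). In co-stimulation genes, KO LPS replicate 2 (7.76) lay below KO LPS replicate 1 (7.97). A shift shared in part by the run therefore stays open. A stronger or longer response to LPS in WT LPS replicate 2 may also be the cause and was not tested. No biological explanation is given by the design.

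Of the interaction calls, 72.9% were lower with TMM. The share was 42.8% with the GC and length correction, 57.1% with DESeq2 size factors and 81.1% with total-count scaling. Across genes, the interaction log2 fold change went with length (Spearman 0.274) and with GC content (-0.173), and that of KO against WT did so in control (-0.264 and 0.137) and with LPS (0.138 and -0.0993). A trend with GC content and length together and the scaling of libraries are therefore candidate explanations of the excess of lower calls, and a difference in genotype effect stays open as untested for that excess.

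The samples were also divided in other ways into groups of the same sizes. In control, 1 of 35 splits, the real one, gave as many calls as the 289 between genotypes (highest other 1). This makes chance unlikely, although 1 of 35 is the smallest share that these samples can give. With LPS, 5 of 100 gave as many as 1294, so chance cannot be excluded by this count. The highest other, 3318, exchanged WT LPS replicate 2 and KO LPS replicate 3, and a split that calls several times the real count points to a structure of the samples. After that exchange, the group holding WT LPS replicate 2 lay at 1.08 to 1.13 on the LPS axis. The group holding KO LPS replicate 3 lay at 0.969 to 1.05, so the split followed that axis. Every KO LPS library also lay beyond the WT LPS libraries other than replicate 2. Genotype and position on the LPS axis are thus not fully separated among the LPS samples. For LPS against control, 1 of 100, the real split, gave as many calls in WT (10246, highest other 9461) and in KO (10338, highest other 9482). Chance is therefore unlikely for these, although 1 of 100 is the smallest share that the splits run can give. In each genotype 126 splits were possible. For the interaction, 2 of 100 gave as many calls as the real 458, namely the real split and another that gave 493. That other split moved WT LPS replicate 2 and KO LPS replicate 3 among 6 libraries. The interaction splits exchanged genotypes within each treatment, which also removes a genotype effect shared by both treatments. They therefore cannot decide whether chance gave the interaction count.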

How the results depend on the processing

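Total-count scaling and the GC and length correction were chosen only after the results were seen. The genes called between genotypes in control (289) were 494 with DESeq2, 895 with only the 2 groups compared, 614 with the replicate block by library number and 822 without the libraries numbered 5 and 7. With LPS (1294) they were 619 with only the 2 groups compared and 3238 without libraries 5 and 7. The interaction (458) gave 813 with DESeq2, 882 with the replicate block by library number and 1591 without libraries 5 and 7. Libraries 5 and 7 are WT and KO LPS replicates 2. Without WT LPS replicate 2 alone, the counts in control, with LPS and for the interaction were 751, 3344 and 1501. Without KO LPS replicate 2 alone they were 292, 1385 and 522. The rises without both libraries therefore went with WT LPS replicate 2. The cause of the other changes was not tested. DESeq2 size factors in edgeR, no filter on low counts, limma-voom, the block by title number, total-count scaling and the GC and length correction moved none of the 5 counts by over 1.5 times. Lists called by camera were 7, 10, 12, 12 and 6 in KO against WT in control, with LPS, LPS against control in WT, in KO, and the interaction. With an estimated correlation they were 0, 0, 0, 0 and 0, and with fry 3, 3, 23, 22 and 3. Between genotypes, fry called the interferon and both MHC lists in control, and the STAT3-linked, cDC1 and lymphocyte lists with LPS. In the interaction it called the STAT3-linked, MHC class II and cDC1 lists.

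Leaving out each library in turn gave 114 (without WT control replicate 3) to 751 (without WT LPS replicate 2) genes between genotypes in control, and 805 (without KO LPS replicate 1) to 3344 (without WT LPS replicate 2) with LPS. It gave 10074 to 10315 genes for LPS in WT, 10185 to 10488 for LPS in KO, and 208 (without WT control replicate 3) to 1501 (without WT LPS replicate 2) for the interaction. Of the values of named genes over the alternatives set beforehand, called or not, 8858 stayed as they were, 212 lost a call, 46 gained it and 0 reversed. With the added alternatives included, 14 of 25 named calls held in every setting in control, 34 of 56 with LPS, 83 of 86 for LPS in WT, 82 of 86 for LPS in KO and 20 of 26 for the interaction. Among the named genes, in LPS against control in KO, Atp5b (-0.13) and Itga2b (-0.074) reversed with total-count scaling, and Ndufv1 (0.11) with the GC and length correction. Over all genes, reversals with total-count scaling were common. For LPS in WT, 9205 genes were called both with TMM and with that scaling, and 7741 of these kept their direction. For LPS in KO, 9391 were called with both, and 7960 kept their direction. With the replicate block by library number, which is checked as a pairing only for LPS in WT, calls of lists by camera changed as follows. In KO against WT with LPS, NF-kB and LPS feedback went from an adjusted p of 0.011 to 0.061, cDC2 markers from 0.071 to 0.022 and glycolysis and hypoxia from 0.071 to 0.0022. In control, glycolysis and hypoxia went from 0.079 to 0.0053 and monocyte and macrophage markers from 0.14 to 0.00021. For LPS in KO, STAT5 and GM-CSF-linked genes (0.14) and cDC1 markers (0.085) both went to 0.0498, and for LPS in WT STAT5 and GM-CSF-linked genes went from 0.12 to 0.045 and glycolysis and hypoxia from 0.062 to 0.035. In the interaction, cDC2 markers went from 0.13 to 0.036 and monocyte and macrophage markers from 0.20 to 0.0016. That block changed the call of no other list. With the block by title number, which no comparison backed as a pairing, the camera adjusted p of glycolysis and hypoxia between genotypes went to 0.035 in control and 0.023 with LPS. For LPS in WT, that list and oxidative phosphorylation (0.057) both went to 0.049. The pseudocount alternative was not run because the values are counts.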

Other observations

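All genes and comparisons in this part were chosen after their values were seen. Ptpn1, a phosphatase that acts on JAK kinases and insulin receptors, rose with LPS in WT from 69.5 to 165 CPM (log2 fold change 1.24 ± 0.06 SE, edgeR adjusted p = 3.9e-13). In KO it was 67.0 CPM in control and 66.3 CPM with LPS (-0.02 ± 0.06, adjusted p = 0.82). KO and WT did not pass as different in control (-0.05 ± 0.07, adjusted p = 0.81), while with LPS Ptpn1 was lower in KO (-1.31 ± 0.06, adjusted p = 3.8e-11), and the interaction was -1.26 ± 0.09 (adjusted p = 9.1e-08).

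Slc15a2, the peptide transporter, was higher in KO in both treatments, at 0.688 and 3.31 CPM in control (2.26 ± 0.27, adjusted p = 8.3e-05) and 10.6 and 50.5 CPM with LPS (2.25 ± 0.16, adjusted p = 1.0e-08). Its interaction was -0.01 ± 0.20 (adjusted p = 0.99).

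Of the genes called in the interaction, 141 fell with LPS in WT, were not called between genotypes in control and were lower in KO with LPS. Another 64 rose with LPS in WT, were not called between genotypes in control and were lower in KO with LPS, and 40 rose with LPS in WT and were higher in KO in control alone. A further 70 rose with LPS in WT and were higher in KO with LPS alone. These classes describe the 458 interaction calls and add no test of their own. With the GC and length correction, 305 of the 458 genes were also called, and 213 of the 498 calls were lower.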
